A study of Mus musculus with 7 samples.

How the data were processed

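The series holds 7 Affymetrix arrays. Brain and kidney antisense signals were each read on a U74A and a U74B array, brain sense signals on a 430A and a 430B array, and kidney sense signals on a 430 2.0 array. Per the labels, tissues were rinsed after dissection and went straight into TRIzol extraction, and biotin-labelled cRNA was made by the standard Affymetrix protocol from 8 micrograms of total RNA for brain and 6.75 for kidney. The deposited values are MAS5 signals, an intensity on a linear scale, per the submitters' processing notes. Per the labels, the authors kept on the U74 arrays only the probe sets that Affymetrix's mask marks as reverse. Probe sequences were not used here, so the orientation of a probe set rests on that mask. The files used here give signals without detection calls, so a floor on the signal stood in their place. The 2% trimmed mean was 198.9 on the kidney 430 2.0 array, 199.2 on 430A and 199.1 on 430B. The reverse subset of the U74 arrays had trimmed means of 47.3 and 29.7 (U74A, brain and kidney) and 73.2 and 67.3 (U74B), and the scaling target of those arrays is not given in the sources used here.

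Genes were named through GEO's platform annotation, with symbols updated through the gene identifier to the RefSeq annotation of assembly GRCm38.p6. On U74A, 1552 reverse probe sets had 1 gene symbol, 17 several and 1042 none, and on U74B 1763, 66 and 1212. On 430A it was 20380, 691 and 1555, and on 430B 14661, 245 and 7605. Probe sets with several symbols or none were counted and not named. No genome coordinates are given, because no build is named for these arrays.

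For antisense, brain and kidney were compared within U74A and within U74B, with signals as deposited. Signals under a pair's floor, the higher of both arrays' 75th percentiles (63.5 for U74A and 98.5 for U74B), were raised to it before the log2 ratio was taken. For sense, each brain array was compared with the same probe sets of the kidney array. Each pair was centred on the median log2 ratio of the probe sets above the median of both arrays, which removed -0.84 from 430A and 2.09 from 430B. The floor was the higher median after centring, 186.4 for 430A and 28.6 for 430B in units of the kidney array. Sense folds are after centring, so they differ from the ratio of the deposited signals printed beside them; a fold is written as at least N-fold where the lower tissue lay below the floor. The 100 probe sets on both 430A and 430B were used once, from 430A, in the tissue comparison, and as the technical repeat. A probe set counted as higher in a tissue at 2-fold or more if it was above the floor in at least 1 tissue.

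A gene was represented by the probe set with the highest mean percentile over both tissues. Sense and antisense were joined by symbol. Their levels were compared as percentiles within each array, and their tissue ratios over genes above the floor on both strands, with 10000 random pairings of the genes as a description of chance. For calls within a tissue (the odds ratios, the shares by sense rank, the genes of highest sense rank and the overlap with other genes), a reverse probe set was counted as above the floor from the 75th percentile of its own array, which was 39.8 and 92.7 on the kidney U74A and U74B arrays and equal to the floor of the pair on the brain arrays. The odds ratio of antisense by sense detection had 0.5 added to each cell. The 24 gene lists, the comparisons and the rule for named genes were fixed before the data were examined. A list's median log2 ratio over members above the floor was set against 10000 random lists of its size matched on mean percentile in 10 bins, where at least 3 members were measured. Symbol-prefix families left out pseudogenes, antisense RNAs and look-alike symbols such as Rps6k, but the noncoding Sox2ot passed this filter and was counted in the homeobox list.

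The rule named the 12 reverse probe sets with the largest ratio each way, the 12 sense genes with the largest ratio each way and the 4 members of each list with the largest ratio. It also named the 10 genes with the highest antisense percentile per tissue, and for the ratio comparison the 8 genes with the largest sum in each direction and the 8 with the largest opposite gap. Lrp2, Eif2s3y and the single list members named for antisense were chosen after their values were seen. With 1 array per group, there is no replicate error, and the number of arrays limits the precision of every value.

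The counting steps were tested on simulated data, made from the real signals with the noise of the technical repeat, and changes were drawn among the brightest 20% of probe sets. Of those changed by 1.5 on the log2 scale, 96 of 100 were recovered on U74A (2611 probe sets), 99 of 100 on U74B (3041), 98 of 100 on 430A (22626) and 91 of 98 on 430B (22411), with 0 unchanged probe sets called. At a change of 3, every changed probe set was recovered on each design. The noise came from the probe sets shared by the brain 430A and 430B arrays (SD 0.25 on the log2 scale), and none was measured on U74. A 2-fold call lies far beyond that noise, so 0 calls among unchanged probe sets followed from the setting and gives no rate of false calls. Alternatives covered scaling, floor, fold threshold, probe sets without a suffix mark, the median of a gene's probe sets, and each array design alone. Scaling 430B to 430A through the shared probe sets, the 430A floor for both, 430A alone and the brightest 10% for shared calls were added after the data were seen. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.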

Results

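Total RNA of dissected mouse brain and mouse kidney was measured on 7 Affymetrix arrays, 3 for sense and 4 for antisense transcripts. The early U74 mouse arrays carried probe sets in the reverse orientation, which pair with RNA running opposite to the annotated transcript. Their signals were taken, per the labels, as a reading of the antisense transcripts of each tissue. Antisense signals were given for 2611 reverse probe sets of the U74A array and 3041 of the U74B array in both tissues. Sense signals came from the 430A array (22626 probe sets) and the 430B array (22511 probe sets) for brain, and from the 430 2.0 array (45037 probe sets), which carries all of these, for kidney. Each tissue had 1 array per design, so no value has a replicate error, no difference was tested across animals and no p-value is given. The median reverse signal was 21.7 in brain and 18.3 in kidney on U74A, and 36.8 and 42.2 on U74B. The median sense signal was 104 on 430A, 121.5 on 430B and 38.8 on 430 2.0.

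The first comparison asked which genes had more antisense signal in brain and which in kidney. In brain, the reverse probe set of Inpp4a, a phosphoinositide phosphatase, read 834.9 against 26.7 in kidney, at least 13.1-fold higher. Bag1, a cofactor of the heat shock protein Hsp70, read 557 against 28.8, at least 8.77-fold higher, and 6430520M22Rik read 853.7 against 6.2, at least 8.67-fold higher. In kidney, the reverse probe set of Rbm47, an RNA-binding protein, read 1283.1 against 19 in brain, at least 13.0-fold higher. Both reverse probe sets of Tmed7, a protein of vesicle transport, were higher in kidney, at 909.7 against 88.8 and 1211.2 against 243.5. Both of Acot2, a mitochondrial acyl-CoA thioesterase, were too, at 1391.6 against 212.2 and 1330.5 against 209.2. The probe sets of Inpp4a, Tmed7 and Acot2 carry a suffix mark (_i_at or _f_at). Those of Tmed7 and those of Acot2 also have neighbouring IDs, so the readings of each pair may not be independent.

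Among genes measured above the floor in both tissues, antisense signal was higher in brain for Dusp9, a MAP kinase phosphatase (890.9 against 106.6), H1f8 (903.2 against 109.4) and Zscan26 (1418.9 against 178.2). It was also higher there for Miip (873.6 against 127.2), Basp1, a membrane protein of growing axons (3106.4 against 482.2), Ndufaf2 (1293.7 against 213.1) and Sfi1 (554 against 112). The reverse probe set of Cdk5r1, the neuronal activator of the kinase Cdk5, was at least 6.38-fold higher in brain, and that of Gpsm2 at least 5.96-fold. In kidney, the cell cycle inhibitor Cdkn1b read 2788.8 against 502. Dnajc3, a chaperone cofactor of the endoplasmic reticulum, was at least 7.01-fold higher in kidney, Sostdc1, a secreted antagonist of BMP signalling, at least 5.42-fold, and the lysosomal peptidase Tpp1 at least 4.99-fold. Tm9sf2 was at least 4.97-fold higher there, Lman1, a cargo receptor between the endoplasmic reticulum and the Golgi, at least 4.10-fold, and Nxt2 at least 4.01-fold. With the floor at the 90th percentile, Lman1 and Nxt2 fell under 2-fold. The reverse probe sets of Dusp9, Miip, Ndufaf2, Cdk5r1, Dnajc3, Tpp1, Tm9sf2 and Lman1 carry a suffix mark. Those of the other genes named in this paragraph carry none.

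Of 723 reverse U74A probe sets above the floor of 63.5 in at least 1 tissue, 208 were 2-fold or more higher in brain, 27 in kidney and 488 in neither. Of 983 on U74B above the floor of 98.5, 141 were higher in brain, 63 in kidney and 779 in neither. By gene, 1009 genes were above the floor, of which 200 were higher in brain and 47 in kidney. Of the 653 U74A probe sets in the brightest 25% of the brain array, 447 (68.5%) were in the brightest 25% of the kidney array too, and on U74B 501 of 760 (65.9%). The same probes sit on both arrays, so their binding strength and background alone would make these lists overlap. The balance of the calls depended on scaling: with each pair centred on its median, U74A gave 122 brain and 59 kidney calls and U74B 154 and 56, and with quantile normalization 72 and 90, and 78 and 100. The median log2 ratio of all genes above the floor was 0.35 as deposited, 0.24 after median-centring and 0.04 after quantile normalization. Reverse probe sets of the same gene differed by an SD of 0.66 on the log2 scale, over 47 genes with more than 1 above the floor.

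**Figure D1:**
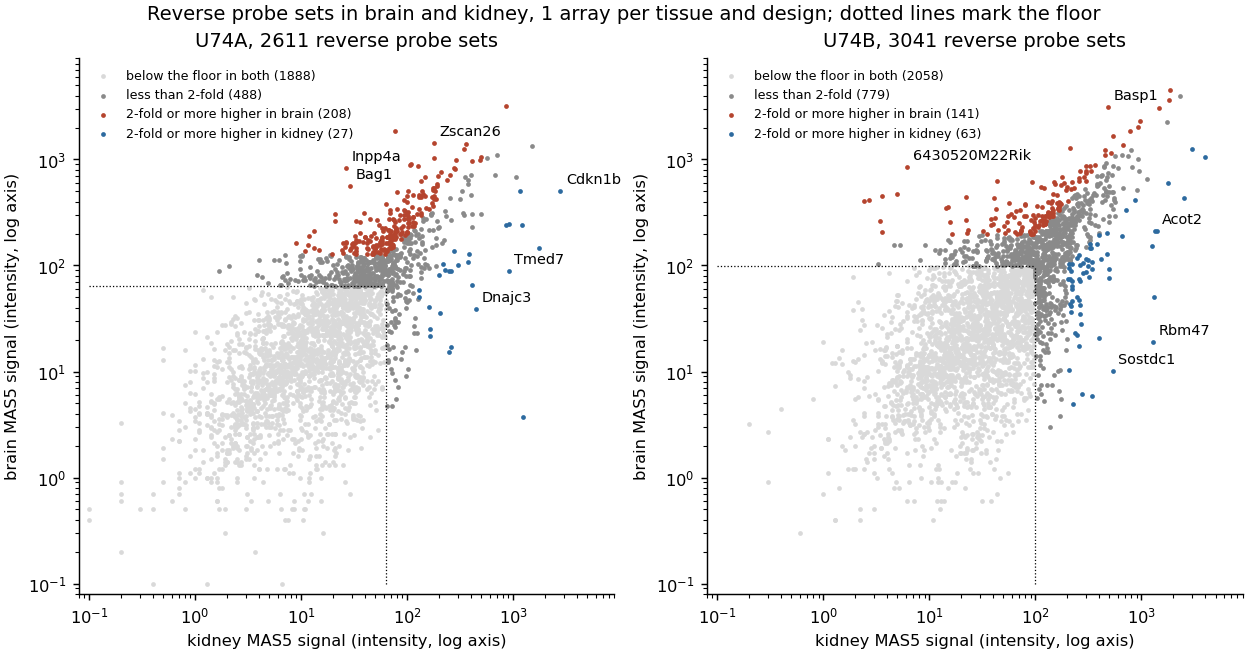
MAS5 signal of each reverse probe set in kidney (horizontal log axis) and brain (vertical log axis) on U74A (left) and U74B (right), with 1 array per tissue and design. Red points are 2-fold or more higher in brain (208 and 141), blue points 2-fold or more higher in kidney (27 and 63), dark grey points less than 2-fold apart, and light grey points lie below the floor (dotted lines, 63.5 and 98.5) in both tissues.

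Few members of the cell type lists had a reverse probe set. Of all 2915 genes with one, 1009 were above the floor in at least 1 tissue. Of 12 neuronal and synaptic genes with one, 8 were above the floor, 3 of them 2-fold or more higher in brain and none in kidney. The median log2 ratio of the 8 was 0.77 (percentile 95.8 of random lists). It fell to 0.50 after median-centring and to 0.32, with 2 of 8 higher in brain, after quantile normalization. The 3 were Pcp4, a calmodulin-binding protein (209.5 in brain and 13.2 in kidney), the synaptic vesicle protein Sv2a (304.1 and 59.4) and the RNA-binding protein Celf4 (322.5 and 144). Calb1, a calcium-binding protein of neurons and of the distal tubule, read 3.8 in brain and 168.9 in kidney. Both astrocyte genes above the floor were higher in brain, the glutamate transporter Slc1a3 (267.1 and 22) and the glycolytic enzyme Aldoc (128.1 and 42.1), though Aldoc and Celf4 fell under 2-fold with quantile normalization, and all 5 with the floor at the 90th percentile. Ndufs7, a subunit of complex I, was 3.67-fold higher in kidney, and Hoxc5 at least 3.83-fold higher in brain, under 2-fold with that higher floor. None of the 3 proximal tubule genes and 7 oligodendrocyte genes with a reverse probe set was above the floor in either tissue. Of the loci with an antisense transcript described in the literature, 4 had a reverse probe set (Bace1, Cav1, Surf2 and Tbp), and none of these was above the floor; that of Bace1 read 96.9 in brain and 11.7 in kidney.

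The sense arrays gave the tissues' own expression for the same comparison. Brain was read on 430A and 430B and kidney on 430 2.0, so array type cannot be separated from tissue here. Neuronal and synaptic genes stood far higher in brain: 54 of 57 were 2-fold or more higher there and none in kidney, with a median log2 ratio of 3.30. Syt1, the calcium sensor of synaptic vesicles, read 8559.8 in brain and 27.4 in kidney (at least 70.5-fold higher), Snap25, a protein of vesicle fusion, 4170 and 0.2 (at least 40.1-fold), and the endocytic GTPase Dnm1 3707.8 and 54.1 (at least 35.7-fold). Of 40 proximal tubule genes, 37 were higher in kidney, with a median of -3.51. They included the lactate transporter Slc5a12 (1357.3 in kidney and 3.4 in brain, at least 47.5-fold), the gluconeogenic enzyme Fbp1 (8749.2 and 79.6, at least 47.0-fold) and Miox, an inositol oxygenase (6048.8 and 64.3, at least 32.5-fold). The only proximal tubule gene called higher in brain was the endocytic receptor Lrp2, by the 430B probe set that represented it, while its probe sets on 430A were higher in kidney (2398.5 against 15.2 and 1059.5 against 9.8). Among random gene lists matched on signal, the medians of the neuronal, astrocyte, oligodendrocyte and ion channel lists lay at percentile 100, and those of the proximal tubule, distal nephron, fatty acid oxidation and choroid plexus lists at percentile 0. The zinc finger median was at percentile 0 too, but its direction depended on the scaling.

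Glial genes followed in brain. Of 18 astrocyte genes 11 were higher in brain and 2 in kidney (median 1.81), led by the glutamate transporters Slc1a2 (8880.8 and 25.8) and Slc1a3 (3678.8 and 28.8). Of 21 oligodendrocyte genes 13 were higher in brain and 2 in kidney (median 2.29), with Mbp, a main protein of myelin, at 6184 against 67.3, Bcas1 at 4539.4 against 32.7 and Cnp at 3252.5 against 349.1. Of 12 genes of microglia and other immune cells, 5 were higher in brain and none in kidney (median 0.93), among them the cathepsin Ctss (569.4 and 364) and the microglial receptor P2ry12 (288.7 and 15.1). As deposited 3 of 13 were higher in brain and Ctss fell under 2-fold, as did P2ry12 with the floor at the 75th percentile. Voltage-gated and related cation channels were 54 in brain and 12 in kidney of 107 (median 1.03), with Kcnq3 and Scn2b among the brain genes and Kcnj15 and Kcnj16 among the kidney genes. Kcnq3 fell under 2-fold with the 430A floor used for 430B.

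Kidney was higher for 19 of 32 genes of the loop of Henle, distal tubule and collecting duct and brain for 2 (median -1.503, but -3.19 without floors and -0.98 with the median of a gene's probe sets), among them Umod, the main protein of urine (7093.2 in kidney and 17 in brain), Cdh16 (6491.9 and 26.6) and the salt cotransporter Slc12a1 (4673.7 and 67). Of 29 genes of fatty acid oxidation, 22 were higher in kidney and 1 in brain (median -2.07), with the thiolase Acaa1b at least 18.3-fold and the dehydrogenase Hadh 14.8-fold higher. Respiratory chain and ATP synthase genes were higher in kidney for 21 of 55 and in brain for none, with a median of -0.92, at percentile 1.52 of random lists matched on signal. These counts moved with the scaling, to 47 of 55 as deposited (median -1.75) and 9 of 55 with quantile normalization (median -0.42). Cytosolic ribosomal protein genes gave 19 of 44 and none (median -0.93, percentile 1.13), 40 of 43 as deposited (median -1.75) and 12 of 45 with quantile normalization (median -0.53). Genes of endothelium, mural cells and fibroblasts were higher in kidney for 13 of 22 and in brain for 2 (median -1.47), led by the collagen Col3a1 (6505.9 and 112) and the smooth muscle actin Acta2 (4384.8 and 241.9). Podocyte genes gave 4 in kidney and 1 in brain of 9 (median -0.74), with Podxl 9.62-fold higher in kidney and Synpo at least 3.46-fold higher in brain, although another of its probe sets was higher in kidney (563.6 against 16.3). That median lay at percentile 10.5 of random lists and shrank to -0.10, with 2 in kidney and 1 in brain, when 430B was brought to the 430A scale, to -0.18 as deposited and to -0.19 with quantile normalization. The choroid plexus list was higher in kidney for 5 of 7 genes (median -3.56, but -0.81 without floors and -1.81 with the median of a gene's probe sets); Calml4, Sostdc1, Kl and Folr1, which led it, are genes that kidney also expresses.

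Solute carriers were 2-fold or more higher in brain for 54 of 283 and in kidney for 107, with a median of -0.29. Homeobox and Sox family genes gave 5 and 17 of 38 (median -0.46), with Emx2, Hoxb3, Hoxc10 and Hoxd8 in kidney and a median of 0.03 once 430B was brought to the 430A scale. Cytochrome P450 genes gave 2 and 9 of 26, with a median of 0.15 (percentile 67.4 of random lists), led by Cyp4a31 and Cyp20a1 in kidney. Zinc finger genes named Zfp gave 32 and 78 of 245 (median -0.48), a direction that turned to 0.52 when 430B was brought to the 430A scale, to 0.51 with signals as deposited and to 0.32 on 430A alone. Genes of ubiquitin conjugation gave 25 and 23 of 111 (median 0.13), led by Fbxl16 and Ube2ql1 in brain, and MAP kinase cascade genes 10 and 10 of 38 (median 0.06), led by Mapk10 and Mapk8ip1 in brain. Imprinted genes gave 12 and 6 of 29 (median 0.45), with the noncoding RNA Meg3, Nnat and Nap1l5 in brain and the cell cycle inhibitor Cdkn1c in kidney. Immediate early and stress genes gave 8 and 3 of 21 (median 0.52), with Nr4a1 and Egr3 in brain and the heat shock gene Hspa1b at least 14.7-fold higher in kidney. Of 15 expression standards, 12 were within 2-fold (median -0.23); Hprt was at least 9.34-fold higher in brain, Rplp0 4.98-fold and Gusb at least 2.49-fold higher in kidney. The sense genes of the loci with described antisense transcripts gave 12 and 10 of 43 (median 0.05). With 430B brought to the 430A scale, which moved the median of all genes from -0.09 to 0.29, solute carriers gave 69 and 79, ubiquitin genes 42 and 7 and MAP kinase genes 13 and 4. With signals as deposited, imprinted genes gave 10 and 10, immediate early genes 6 and 6, and 8 of the standards were higher in kidney. Hoxc10, Egr3 and Ube2ql1 fell under 2-fold with the 430A floor used for 430B.

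Several measured values concern what the preparations held. Of 12 genes of blood, fat and adrenal gland, 1 was higher in brain and 3 in kidney (median -0.05). Fabp4 and Adipoq, which fat cells express, were higher in kidney (4989.2 against 24 and 616 against 4.8), as was the platelet gene Pf4, although Adipoq and Pf4, like Synpo and Gusb above, fell under 2-fold with the floor at the 75th percentile. Chga, a protein of neuroendocrine granules, was higher in brain (698.4 against 18.4). The pituitary hormones Gh and Prl were among the brain genes with the largest ratios, at 5129.1 against 33.8 and 4519.1 against 1.6. Xist, the noncoding RNA of the inactive X chromosome, read 1421.7 in brain and 37.6 in kidney, and the Y-linked Eif2s3y read 1.1 in brain and 339.9 in kidney, so the tissues differed in sex-linked genes as well; the labels name no sex.

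The largest sense ratios towards brain belonged to Slc1a2, Syt1, Mbp, Gh, the elongation factor Eef1a2, Prl, Rtn1, Rph3a, Snap25, the kinesin Kif5c, Dnm1 and the tubulin Tubb4a, between at least 34.0-fold and at least 73.1-fold; with 430B brought to the 430A scale, 7 of them stayed among the 12 largest. Those towards kidney belonged to the basement membrane collagen Col4a4, Tmem52b, Gcnt1, Tmem174, Slc16a12, Smim4, Kcnj15, Cobll1, Mfsd4b1, Mecom, Slc5a12 and Fbp1, between at least 47.0-fold and at least 81.9-fold. All of these kidney genes but Fbp1 were read on 430B, so their order rests on centring that design by itself: at the 430A scale, Col4a4 was at least 27.02-fold and Slc5a12 at least 15.7-fold higher, and only Fbp1 stayed among the 12 largest. None of these 24 genes turned direction or fell under 2-fold under the other scalings and floors tried. Of 13364 probe sets of 430A above the floor, 2649 were 2-fold or more higher in brain and 2814 in kidney, and of 13358 of 430B, 2488 and 3191. On 430B the balance rested on centring that design by itself: brought to the 430A scale through the 100 probe sets on both brain arrays, it gave 4332 brain and 735 kidney calls, and with signals as deposited 4863 and 432 (430A 1515 and 5358). Those 100 probe sets also gave the only repeat reading of 1 tissue, with an SD of 0.25 on the log2 scale over the 98 above the median on both arrays. Of these 98, 1 was 2-fold or more apart after centring.

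**Figure D2:**
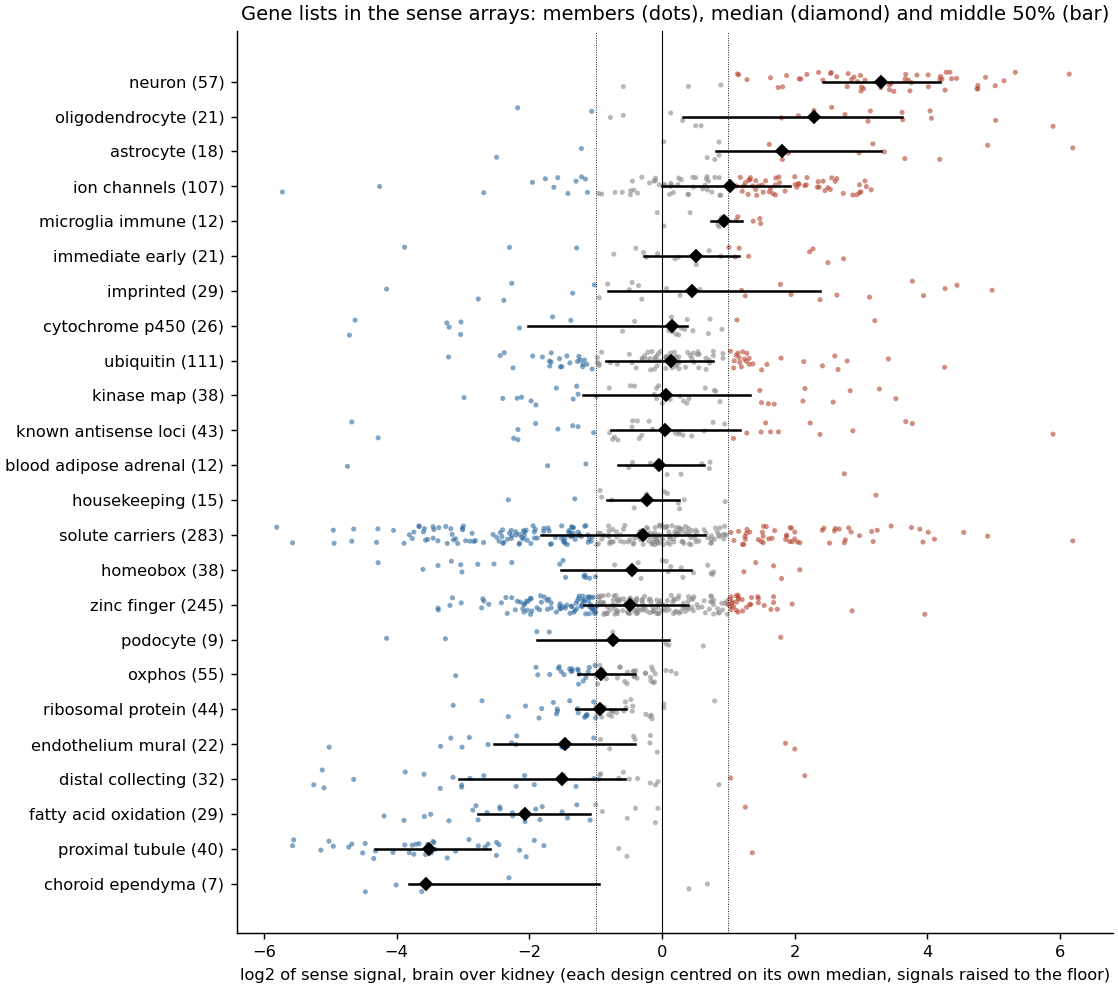
Log2 ratio of brain over kidney sense signal for the measured members of the 24 gene lists fixed before the data were examined, with each array design centred on its own median. Dots are genes (red 2-fold or more higher in brain, blue in kidney), diamonds are list medians and bars the middle 50% of members; the medians run from 3.30 for neuronal genes to -3.56 for the choroid plexus list. The zinc finger median turns to 0.52 with 430B brought to the 430A scale.

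The next comparison set sense and antisense levels of the same genes side by side within a tissue, for 2830 genes with a reverse and a sense probe set. Ranks within each array were used, which do not remove differences in binding strength between probes, so the values of this comparison still carry them. Brain sense signals were ranked on each brain array by itself, and kidney sense signals over the whole kidney array. A given sense percentile therefore does not mean the same in both tissues. In brain, the highest antisense ranks belonged to Sfpq, a splicing factor (antisense percentile 99.95 and sense percentile 79.7), the arginine methyltransferase Prmt7 (99.92 and 67.5), Zscan26 (99.90 and 76.8) and Basp1 (99.88 and 99.2). Ogfr, Pcbp2, Cdc34, Zbtb7a, Gnl3l and Cbx3 followed, with sense percentiles from 48.6 for the chromatin protein Cbx3 to 97.3 for Gnl3l. In kidney they belonged to Cdkn1b (99.98 and 90.9), the G protein subunit Gng2 (99.95 and 91.4), the RNA-binding protein Pcbp2 (99.90 and 98.9), Sfpq (99.88 and 94.9) and Tmed7 (99.83 and 97.8). Prmt7, Eef1b2, Sf3b2, Septin10 and Acot2 followed, with sense percentiles from 79.9 for Prmt7 to 99.1 for the elongation factor Eef1b2. Sfpq, Prmt7 and Pcbp2 were among the first 10 of both tissues. The reverse probe sets of Sfpq, Prmt7, Cdc34, Gng2, Tmed7, Sf3b2 and Acot2 carry a suffix mark.

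Across genes, Spearman's rho of the sense and antisense percentiles was 0.051 in brain (central 95% of random pairings -0.036 to 0.037) and 0.18 in kidney (-0.036 to 0.038); genes are not independent replicates. On U74A alone the brain value was 0.018, inside its random range (-0.053 to 0.054), and on U74B alone it was 0.073, outside it (-0.049 to 0.051). With sense read on 430A alone, where all brain sense ranks came from a single array, rho was 0.053 in brain and 0.18 in kidney. Here a reverse probe set was counted against the 75th percentile of its own array (63.5 in brain and 39.8 in kidney on U74A, 98.5 and 92.7 on U74B) in place of the floor of the pair. In kidney, a reverse probe set was above that level for 30.3% of the 1972 genes with sense signal above its floor and for 24.5% of the 858 without (odds ratio 1.34). In brain the shares were 28.1% of 2038 and 30.2% of 792 (odds ratio 0.90), an order that turned under 3 of the settings tried. From the 20% of genes with the lowest to the 20% with the highest sense rank, the share of genes with antisense signal above that level went from 21.2% to 37.6% in kidney and from 29.3% to 28.4% in brain. The sense ranks behind these last shares were formed differently in the tissues, so the shares are not directly comparable between them.

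The main comparison of sense with antisense used the ratio between tissues, in which each probe is set only against itself. On the sense strand the tissues were still read on different array types, which cannot be separated from the tissue. Genes whose sense signal was 4-fold or more higher in brain had more antisense signal there too: their median antisense log2 ratio was 0.79 over 45 genes, 17 were 2-fold or more higher in brain and none in kidney. Genes with sense 4-fold or more higher in kidney had a median antisense log2 ratio of -0.05 over 96 genes, with 13 higher in brain and 13 in kidney, against 0.33 over the 436 genes with sense less than 2-fold apart. Among genes higher in brain on both strands were Slc1a3 (antisense at least 2.71-fold, sense 30.04-fold), Pcp4 (at least 3.30-fold and at least 18.3-fold), Cdk5r1 (at least 6.38-fold and at least 8.56-fold) and Inpp4a (at least 13.1-fold and at least 3.39-fold). Stmn3, Ppp3ca, Aldoc and Sv2a completed the 8 with the largest sums, of which Stmn3 (antisense 1.96-fold) stayed under 2-fold. Among genes higher in kidney on both strands were Rbm47 (at least 13.0-fold and 32.1-fold), Smim4 (3.47-fold and at least 53.4-fold), Acot2 (6.56-fold and at least 21.5-fold) and Sostdc1 (at least 5.42-fold and at least 16.1-fold). Tmprss2, S100g, Dnajc3 and Fosl2 completed that set, of which S100g (antisense 1.26-fold) and Fosl2 (at least 1.56-fold) stayed under 2-fold on the antisense strand. The sense folds of Rbm47, Smim4 and Acot2 come from 430B, and at the 430A scale they were 10.6-fold, at least 17.6-fold and at least 7.09-fold. The reverse probe sets of Cdk5r1, Inpp4a, Ppp3ca, Smim4, Acot2, Tmprss2 and Dnajc3 carry a suffix mark, as do the sense probe sets of Slc1a3, Aldoc and Tmprss2.

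Other genes ran in opposite directions. The ubiquitin ligase Rnf185 had antisense signal 2.32-fold higher in brain and sense signal 27.9-fold higher in kidney, and Suclg2, a subunit of succinyl-CoA ligase, 2.04-fold and 25.01-fold, where both sense folds come from 430B and were 9.19-fold and 8.25-fold at the 430A scale. Bag1 had antisense signal at least 8.77-fold higher in brain and sense signal 2.75-fold higher in kidney, and Rabep2 at least 4.77-fold and 6.85-fold (2.26-fold at the 430A scale). Mettl7b, Kdm1b and Cth ran the same way, and Palld did with an antisense ratio of only 1.18-fold. A suffix mark is carried by the probe sets of Rnf185 and Rabep2 on both strands, of Mettl7b on the antisense strand and of Suclg2 on the sense strand. Whether both strands read the same gene there was not checked. The probe sets of Bag1, Kdm1b, Cth and Palld carry none. The antisense ratios of Suclg2, Mettl7b and Kdm1b fell under 2-fold with antisense median-centred, as did those of Rnf185 and Cth with quantile normalization. On the antisense strand, 155 of all 806 genes compared were 2-fold or more higher in brain and 45 in kidney. Of the 135 genes with sense 2-fold or more higher in brain, 39 were 2-fold or more higher in brain on the antisense strand and 2 in kidney. Of the 235 with sense higher in kidney, 36 were higher in brain and 26 in kidney, an order that turned to 25 and 30 of 245 with antisense median-centred and 7 and 50 of 261 with quantile normalization. With 430B brought to the 430A scale, the sense groups themselves changed. Antisense was then higher in brain and kidney for 48 and 4 of 188 genes with sense higher in brain. For the 152 genes with sense higher in kidney it was 26 and 22.

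Across all 806 genes above the floor on both strands, Spearman's rho of both ratios was 0.28 and Pearson's r 0.31, while 10000 random pairings of the genes gave rho up to 0.12. The median of the 45 brain genes lay at percentile 100 of random gene lists matched on antisense signal (central 95% 0.04 to 0.51), and that of the 96 kidney genes at percentile 0 (0.12 to 0.45). Those lists were matched on signal and not on array design, and the lower antisense ratio of the kidney genes was seen on U74B alone. There the median was -0.17 over 67 genes, against 0.20 for genes with sense less than 2-fold apart, at percentile 0.035 of random lists of that design. On U74A it was 0.56 over 29 genes against 0.49, at percentile 51.0. The brain genes had medians of 0.97 over 9 genes on U74A and 0.73 over 36 on U74B, at percentiles 98.04 and 100.

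**Figure D3:**
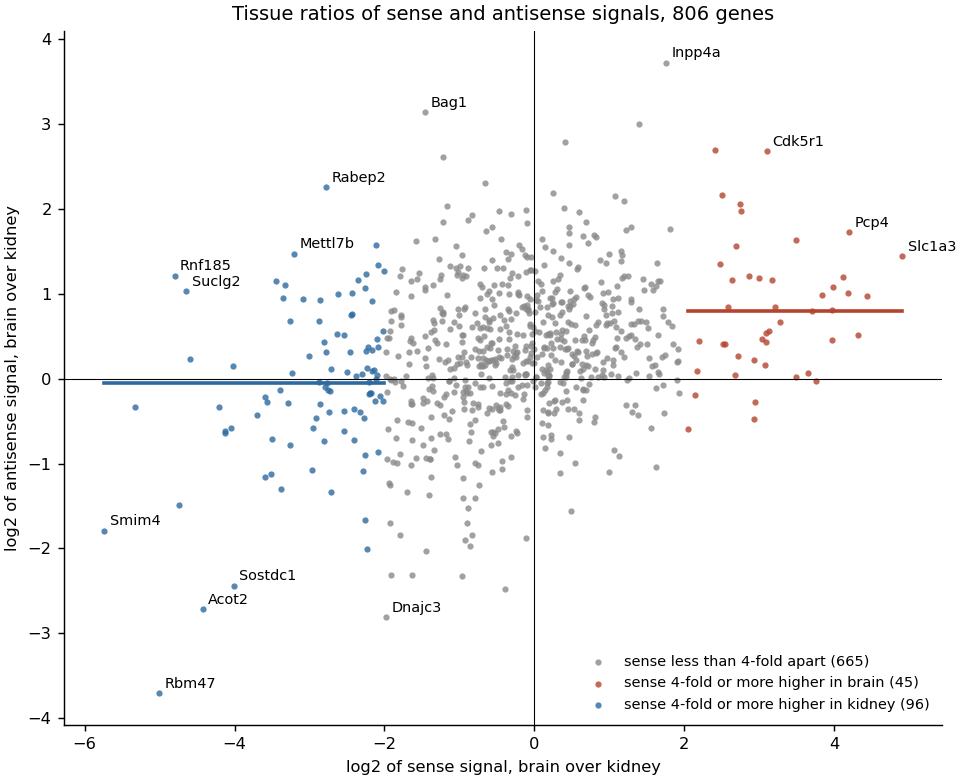
Log2 ratio of brain over kidney for sense signal (horizontal axis) and antisense signal (vertical axis) of 806 genes. Red points have sense signal 4-fold or more higher in brain (45 genes, antisense median 0.79, red line), blue points 4-fold or more higher in kidney (96 genes, antisense median -0.05, blue line); grey points lie between.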

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

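Of the tests below, those on probe sets that match several transcripts and on each array design alone were chosen after the result was seen; the others were written down before, but the use of single hormone and Y-linked levels beside them came after.

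As deposited, antisense was 2-fold or more higher in brain in 36 of the 235 genes with sense 2-fold or more higher in kidney. The reverse held in 2 of the 135 genes with sense higher in brain. Over all 806 genes, antisense was higher in brain in 155 and in kidney in 45. Both opposite groups were thus smaller than the shares over all genes would give. The opposite counts were 25 and 1 with antisense median-centred, 7 and 4 with quantile normalization, and 26 and 4 with 430B brought to the 430A scale. The 7 given here are those of the 36 among the 8 genes named for the largest opposite gaps. The difference between the strands was not tested, since each tissue has 1 array per design. The gap between both log2 ratios was 6.01 for Rnf185 and 5.67 for Suclg2, and at least 5.03 for Rabep2, 4.67 for Mettl7b, 4.60 for Kdm1b, 4.59 for Bag1 and 4.43 for Cth, whose lower signal on 1 strand lay below the floor, so that the order of these 5 is not measured. The antisense ratios of Suclg2, Mettl7b and Kdm1b fell under 2-fold with antisense median-centred, and those of Rnf185 and Cth too with quantile normalization. Rnf185, Suclg2, Rabep2 and Kdm1b have their sense probe set on 430B, whose ratios move by 1.60 towards brain when it is scaled to 430A. The probe sets of Rnf185 and Rabep2 on both strands, of Mettl7b on the antisense strand and of Suclg2 on the sense strand carry a suffix mark.

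The antisense and sense ratios between the tissues rose together across genes, with a Spearman's rho of 0.28 over 806 genes. Of the 235 genes with sense higher in kidney, 36 had antisense higher in brain and 26 in kidney as deposited. Over all 806 genes these numbers were 155 and 45. The genes with sense higher in kidney thus had a smaller share in brain and a larger one in kidney than all genes. For the genes with sense higher in kidney, the counts were 25 and 30 of 245 median-centred, against 121 and 56 of all 844 genes. They were 7 and 50 of 261 with quantile normalization, against 57 and 97 of 888. With 430B brought to the 430A scale they were 26 and 22 of 152, against 149 and 45 of 793. Probe sets with a suffix mark do not account for the correlation by themselves, because rho stayed at 0.24 with only unmarked probe sets. Whether unmarked probe sets match several transcripts was not checked, so that explanation is not excluded. A single design does not account for rho either, because the lower of the values on U74A and U74B alone was 0.24. The lower antisense ratio of genes with sense higher in kidney was seen on U74B alone (-0.17 there and 0.56 on U74A). Antisense cRNA copied from abundant sense RNA during labelling stays open. Of genes at or over the 95th sense percentile, 36.3% had a reverse probe set above the 75th percentile of its own array over both tissues, with 29.5% in brain and 43.5% in kidney, against 28.7% and 28.6% of all genes; by the bounds set per tissue, over 50% for and up to 35% against, brain counts against that explanation and kidney lies between. The 95th sense percentile was taken on each brain array by itself and over the whole kidney array, so the shares of the tissues are not directly comparable. Shared regulation of both strands in a tissue stays open too, as untested, so the pattern may be biological, come from labelling or have another source. The orientation of the reverse probe sets, which rests on the mask, was not checked against probe sequences.

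Gh and Prl read 5129.1 and 4519.1 in brain. Pituitary tissue left on the brain is a candidate source, and probe sets of single hormones that pick up another transcript are the other; they cannot be told apart here. The 15 other pituitary genes measured had a median brain percentile of 47.3, low enough to count against the first by the bound set beforehand. That bound was wrong for a small admixture, since only 6 of the 15 lay above the sense floor in brain, and the hormone genes Pomc (percentile 99.4, 3041.6 against 52.7 in kidney) and Cga (90.9, 612 against 16.6) stood high. Tshb, Lhb and Fshb did not (percentiles 52.5, 46.0 and 4.35), and brain itself expresses at least 4 genes of the list (Pomc, Crhr1, Pcsk1 and Chga).

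Xist stood at percentile 97.3 in brain and 49.4 in kidney on its brightest probe set. A female brain and a male kidney, or a lower level of Xist in kidney of the same sex, cannot be told apart by the test set beforehand, which asked for at least 2 Y-linked genes above the floor in kidney alone and found 1. That gene was Eif2s3y, at percentile 82.2 in kidney and 0.46 in brain. The other Y-linked probe sets lay below the floor in both tissues and ran both ways after centring, with 3 of Uty higher in kidney and 1 in brain, 1 of Kdm5d higher in kidney and 2 in brain, and the other one of Eif2s3y higher in kidney (18.4 against 15.9 as deposited). The brightest of Uty and of Kdm5d were higher in kidney, at 138.2 against 42.9 and 129.7 against 17.5 as deposited. Those of Kdm5d higher in brain were dimmer, at 44 against 12.7 and 19.1 against 2.7. That of Uty read 30.2 in brain and 43.3 in kidney as deposited, an order that centring turned. If the sexes differed, part of the tissue differences could be sex differences, and the design gives no value that separates these.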

How the results depend on the processing

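Of the settings here, scaling 430B to 430A, the 430A floor for 430B and 430A alone were chosen after the data were seen. No paired analysis was possible because each group holds 1 array, and no replicate could be left out. With no detection calls, the floor sets how much dim signal counts. The cause of a change was not tested unless named. Antisense calls (brain and kidney on U74A, then on U74B, from 208, 27, 141 and 63) were 122 and 59 on U74A with median-centring, 72, 90, 78 and 100 with quantile normalization, which evens both arrays by construction, 491, 118, 304 and 235 with the floor at the median, 71, 13, 45 and 17 at the 90th percentile, 936, 455, 605 and 795 without a floor, 66, 13, 33 and 20 at 3-fold, and 113, 10, 84 and 27 with unmarked probe sets only, where fewer were counted. Sense calls (430A, then 430B, from 2649, 2814, 2488 and 3191) were 1340, 1527, 1137 and 2010 at 3-fold, 1515, 5358, 4863 and 432 as deposited, 9731, 4645, 7636 and 5715 without a floor, 1043 and 1693 on 430A and 909 in brain on 430B with the floor at the 75th percentile, and 1422 in kidney on 430A with unmarked probe sets. On 430B they were 4332 and 735 scaled to 430A, and 206 and 957 with the 430A floor. The odds ratio of antisense by sense detection in brain turned from 0.90 to 1.20 with the antisense floor at the median, 1.11 with the sense floor at the 75th percentile and 1.01 with the median of a gene's probe sets. The antisense median of genes with sense higher in brain moved from 0.79 to 0.54 at the 90th percentile floor, 0.43 with quantile normalization, which took that of genes with sense in neither tissue from 0.33 to 0.00151, and 1.08 with 430A alone; that of genes with sense higher in kidney moved from -0.05 to 0.56 on U74A alone. The homeobox median in sense turned from -0.46 to 0.87 without floors and 0.033 with 430B scaled to 430A, the immediate early and imprinted medians from 0.52 and 0.45 to -0.13 and -0.19 as deposited, the antisense ubiquitin median from 0.48 to -0.036 with quantile normalization, and the zinc finger median from -0.48 to 0.51 as deposited, 0.52 with 430B scaled to 430A and 0.32 with 430A alone. Of the named sense list members, Adipoq, C1qb, Gusb, Ighm, P2ry12, Pf4, Rps6 and Synpo fell under 2-fold with the floor at the 75th percentile, Ctss, C1qb and Mapk1ip1l as deposited, where Tcf21 turned, and Cyp2j11, Egr3, Fbxo5, Hoxc10, Kcnq3, Tcf21 and Ube2ql1 with the 430A floor. The correlations of ratios moved by less than 0.1, while that of levels in brain ran from 0.018 on U74A alone to 0.073 on U74B alone. Of the brightest 10% of brain reverse probe sets, 62.8% on U74A and 57.2% on U74B were also in that of kidney. Of 168 list medians, 26 changed sign, 8 of them from a median over 0.25 in size and 18 from a smaller one; 86 kept their sign and moved by up to 0.25, and 56 moved further. That value is the technical SD of single probe sets, not the spread of a list median.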

Other observations

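Among the sense genes of the homeobox list, the kidney side held Hoxd8 at 1683.6 in kidney and 51.6 in brain, Hoxa10 at 1527.5 and 3.8, and Hoxd9 at 1508.3 and 28.7, among other Hox genes. On the brain side stood Sox10, a factor of oligodendrocytes (362.4 in brain and 43.9 in kidney), Sox2 (244.5 and 7.3) and its overlapping noncoding RNA Sox2ot (512.7 and 2.3), without which the list gave 4 genes in brain and 17 in kidney of 37 (median -0.47). Of the inward rectifier potassium channels, Kcnj15, Kcnj16 and Kcnj1 were higher in kidney (1509.2, 1236.8 and 1200.7, against 14.1, 274.8 and 3.4 in brain), while Kcnj10 was higher in brain (578 against 233.1). These genes were chosen after their values were seen.

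Reverse probe sets without a single gene symbol were above the floor somewhat less often than those with 1 symbol. Of 2337 such probe sets, 646 (27.6%) were above the floor, with 140 higher in brain and 39 in kidney, against 1060 of 3315 (32.0%) with 1 symbol, of which 209 were higher in brain and 51 in kidney.

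A hypothesis was that antisense signal lies at genes that overlap another annotated gene. Of 2897 genes with a reverse probe set and a position in the RefSeq annotation of GRCm38.p6, 1330 overlapped another gene on either strand. Of these 502 (37.7%) were at or above the 75th percentile of their own array in at least 1 tissue, against 596 of 1567 (38.0%) of the others, which is percentile 43.2 of random gene lists of that size. Overlap of gene bounds on either strand therefore did not mark the genes with antisense signal. Strand was not used, so the test cannot decide whether antisense signal lies at genes that overlap another gene on the opposite strand.

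Genes with probe sets above the floor in both tissues on both 430A and 430B read lower on 430B by a median of -0.61 on the log2 scale (brain over kidney, 807 genes) with each design centred by itself, and higher by 0.32 (493 genes) with 430B scaled to 430A. At matched kidney signal, over 10 bins, probe sets of both designs differed by -0.09 under the latter scaling.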
